A study of Homo sapiens with 2 samples.

How the data were processed

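Small RNA libraries were made from K562 cells, a human erythroleukaemia cell line that grows in suspension and carries features of red cell and megakaryocyte precursors. One library came from cells transduced with a lentivirus carrying GFP, the control, and 1 from cells transduced with a lentivirus overexpressing QKI5, the nuclear isoform of the RNA-binding protein Quaking. Per the labels' protocols, a kit for miRNA isolation enriched the small RNA, an Ion Torrent RNA-seq kit served for the libraries, and an Ion Proton instrument read them. The submitters' processing notes name Bowtie 0.12.3 and the genome build hg19. The miRNA annotation, the allowed mismatches, the treatment of reads that map to several miRNAs and the use of strand are not given in the sources used here.

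The deposited table has 1 value per library for 2218 mature miRNAs. Its name calls the values RPKM, but the values the authors deposited are RPM, reads per 1000000 reads of the library: in each column every value above 0 was a whole multiple of a single step, the same for every miRNA, within a tolerance of 0.1 of a read. The step was 0.0430 RPM in the GFP library and 0.153 RPM in the QKI5 library, and 100.0% of the values above 0 came out whole in both. One step is 1 read, so the library totals the values were scaled by were 23262340 reads for GFP and 6553945 reads for QKI5. What the authors counted in those totals is not given in the sources used here. The listed miRNAs held 66.3% of the GFP total (95% Wilson interval 66.26% to 66.30%) and 59.5% of the QKI5 total (59.45% to 59.53%).

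The design fixed before the data were examined had assumed RPKM or raw counts. The log2 ratio of QKI5 over GFP was computed on log2(RPM + pseudocount), with a pseudocount of 0.153 RPM, which is the larger of the smallest values above 0 of the libraries. This scale understates the ratio of miRNAs with few reads. Folds quoted in the text are plain ratios of RPM, with an exact conditional binomial (Clopper-Pearson) 95% interval from the recovered reads. Such intervals, and the upper limit of 3 reads set for a count of 0, cover counting error only. Reads without molecular identifiers are not independent molecules. There was 1 library per group, so no difference has a replicate check, no spread between cultures could be estimated, and no p-value for the effect of QKI5 is given. A miRNA was counted as higher or lower when the log2 ratio was at least 1 in size among the 200 miRNAs with the highest mean of the 2 libraries.

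A total of 22 lists of miRNAs (families, genomic clusters, blood lineages, fragments of other RNAs and markers of other cell types) were fixed before the data were examined. Names were matched without regard to arm, so both arms of a hairpin counted as members of a list. Each list's median log2 ratio was taken over its members with a read in either library and placed among 10000 random lists of the same size, in which each member was replaced by 1 of the 40 miRNAs nearest to it in mean level. A list whose percentile lay below 2.5 or above 97.5 is called outside the central 95%. This describes these libraries and is not a test of the treatment. A list's floor median was the median of plain log2 ratios, without the pseudocount, over members above 3 reads in either library. Counts of 0 were set to 3 reads in it. The text names miR-124, the 10 most abundant miRNAs of each library, the 12 highest and 12 lowest log2 ratios among the 200, the 3 highest values each way among less abundant miRNAs at 0 in 1 library, and from each list its most abundant member and the 2 members with the largest log2 ratio in size among the 400 most abundant miRNAs. A few other members were chosen as examples after their values were seen.

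Hairpin sequences, host genes and neighbours came from GENCODE release 29 on GRCh38. Since the authors mapped to hg19, no positions are given and the annotation served only for sequence, host gene and adjacency. Of the 400 most abundant miRNAs, 399 had a hairpin. The GC content of a mature miRNA was approximated by that of its 5p or 3p side of the hairpin, or by that of the whole hairpin where the name gives no arm. Alternatives covered the pseudocount, the scaling of the columns, the level filter and the fold threshold. Alternatives chosen after seeing the data were rescaling to the sum of the listed miRNAs, thinning the GFP reads to the QKI5 total, removal of a linear GC trend, and an exact binomial test of the recovered reads with Benjamini-Hochberg adjustment at 0.05. That test compares these 2 libraries, not the conditions, and called 426 of 1995 detected miRNAs. A model with an estimated dispersion could not be fitted with 1 library per group. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. On data simulated for the QKI5 and GFP libraries, with 200 of the 400 most abundant miRNAs changed, 100.0% of those changed by 2 on the log2 scale and 97.0% of those changed by 1.3 were counted at 2-fold, against 0.0% of 200 unchanged ones. These shares hold for counting error alone.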

Results

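Mature miRNAs were profiled by small RNA sequencing in K562 erythroleukaemia cells carrying a GFP lentivirus and in K562 cells carrying a QKI5 lentivirus, with 1 library in each group. The question was which miRNAs differ in abundance when QKI5 is overexpressed. The GFP library rested on 23262340 reads, of which 15418197 were on listed miRNAs. The QKI5 library rested on 6553945 reads, of which 3899030 were on listed miRNAs, so the GFP library was 3.55 times as deep. Of 2218 listed miRNAs, 1812 had a read in the GFP library, 1448 in the QKI5 library and 1265 in both. The 200 most abundant miRNAs had at least 119 reads in either library and held 99.4% of the miRNA reads of the GFP library and 99.2% of those of the QKI5 library. Their levels were ranked alike in both libraries (Spearman's rho across miRNAs 0.893, which is not a measure of replicate error). The QKI5 transcript itself was not analysed here, so the overexpression was not checked from these data. All differences below compare 1 library with 1 library and have no replicate check.

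miR-124, a miRNA abundant in neurons whose primary transcript earlier work tied to QKI5, was barely detected. miR-124-3p had 1 read in the QKI5 library and 0 in the GFP library, and miR-124-5p had 0 and 2 reads. A count of 0 allows up to 0.458 RPM in the QKI5 library and 0.129 RPM in the GFP library, so a difference in mature miR-124 was not detectable at this depth. GENCODE places its 3 hairpin genes on chromosomes 8 and 20, with MIR124-1 in an exon of LINC00599. The list of miRNAs that earlier work tied to QKI proteins also held miR-7 and miR-20a. miR-7-5p was at 164 RPM in the QKI5 library and 179 RPM in the GFP library, a ratio of 0.917 (95% counting interval 0.857 to 0.981). The hairpin of miR-3529 lies antisense to a miR-7 hairpin, so these reads may not be separate. There were 0.655 miR-7-5p reads per miR-3529-3p read in the QKI5 library and 0.542 in the GFP library. miR-20a-5p was 1.53-fold lower in the QKI5 library (1.51 to 1.55) and miR-20a-3p 1.88-fold lower (1.79 to 1.97). None of the 4 list members among the 400 most abundant miRNAs differed by 2-fold. The median log2 ratio of the 7 detected members was -0.13, at percentile 37.1 of random lists, and its sign turned to 0.03 when the columns were rescaled to the sum of the listed miRNAs.

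miR-19 miRNAs, made from the oncogenic miR-17-92 cluster and a paralog of it, dominated both libraries. miR-19b-3p and miR-19a-3p together made up 60.9% of the miRNA reads in the GFP library and 48.4% in the QKI5 library. How any reads matching both were assigned is not given in the sources used here. miR-19a-3p, from an exon of the host gene MIR17HG on chromosome 13, was at 199735 RPM in the GFP library and 122726 RPM in the QKI5 library, 1.63-fold lower (1.62 to 1.63). miR-19b-3p, which has hairpin genes on chromosomes 13 and X and whose reads cannot be assigned to 1 of them, was 1.23-fold lower (1.23 to 1.24) and miR-18a-5p 1.73-fold lower (1.72 to 1.74). Among the other abundant miRNAs, miR-376c-3p was at 22639 RPM with QKI5 and 27697 RPM with GFP, a log2 ratio of -0.29 that turned to 0.26 with a linear trend on GC content removed. miR-381-3p was 1.81-fold lower with QKI5 (1.78 to 1.83). The leukocyte miRNAs miR-142-3p and miR-223-3p differed little, with ratios of 1.17 (1.16 to 1.18) and 1.04 (1.03 to 1.05). The ratio of miR-223-3p was below 1 under quantile normalization, under a trimmed mean and when the 10 most abundant miRNAs were left out of the scaling. miR-16-5p was 1.79-fold higher with QKI5 (1.78 to 1.81) and miR-21-5p 1.67-fold higher (1.66 to 1.69).

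Of the 200 most abundant miRNAs, 30 were at least 2-fold higher in the QKI5 library, 14 were at least 2-fold lower, and 156 lay within 2-fold. The counting interval lay wholly beyond 2-fold for 24 of the 30 and 13 of the 14. Higher ratios thus made up 68.2% of the calls, against 47.4% under quantile normalization and 56.1% when the 10 most abundant miRNAs were left out of the scaling, and 77.4% when the columns were rescaled to the sum of the listed miRNAs. Under all 10 settings of scaling, pseudocount, depth and composition compared, 14 miRNAs stayed at least 2-fold higher and 10 at least 2-fold lower. The SD of the log2 ratio across these 200 miRNAs was 0.86 around a median of 0.06.

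miR-197-3p stood highest among the 200, at 905 RPM in the QKI5 library and 71.7 RPM in the GFP library, 12.6-fold higher (11.9 to 13.3). Its hairpin lies within an exon of a GNAI3 transcript on chromosome 1. miR-2392, from an intron of MEG3 on chromosome 14, was 6.60-fold higher (6.14 to 7.10). miR-539-5p, from the same imprinted region, was 4.0-fold higher (3.57 to 4.49), and miR-423-3p was 3.90-fold higher (3.59 to 4.24). The most abundant miRNAs in this group were miR-126-3p and miR-27a-3p. miR-126-3p, made from an intron of EGFL7 and known from endothelium and blood precursors, was at 38674 RPM with QKI5 and 14362 RPM with GFP, 2.69-fold higher (2.68 to 2.71). miR-27a-3p was at 32157 and 11118 RPM, 2.89-fold higher (2.88 to 2.91). The rest of the 12 highest were miR-660-5p (3.13-fold), miR-4286 (3.13-fold), miR-192-5p (3.02-fold), miR-941 (3.0-fold), miR-769-5p (2.93-fold) and miR-1275 (2.71-fold). miR-941 has 5 hairpin copies in an intron of DNAJC5, so its reads cannot be assigned to 1 of them. miR-126-3p and miR-27a-3p were just under 2-fold with quantile normalization, at log2 ratios of 0.99 and 0.94, and miR-941 was at 0.94 with the GC trend removed.

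miR-369-3p, from an intron of MEG9 on chromosome 14, was lowest with QKI5, at 18.2 RPM against 120 RPM with GFP, 6.60-fold lower (5.50 to 8.0). miR-361-5p, from an intron of CHM on chromosome X, was 3.71-fold lower (3.17 to 4.36), and miR-4456 3.37-fold lower (2.95 to 3.86). miR-154-3p, at 1012 RPM with GFP, was 3.17-fold lower (3.03 to 3.31). The 14q32 miRNAs miR-136-3p, miR-758-3p, miR-495-3p and miR-543 were 2.66-, 2.33-, 2.32- and 2.24-fold lower. With the GC trend removed the log2 ratios of miR-495-3p and miR-543 were -0.94 and -0.87. The remaining members of the 12 lowest were miR-550a-3p (2.66-fold), miR-1307-5p (2.65-fold), miR-550b-2-5p (2.42-fold) and miR-652-5p (2.29-fold). miR-550a-3p has 3 hairpin genes, all on chromosome 7, and its reads cannot be assigned to 1 of them. Below the 200, the highest miRNAs with 0 reads in the GFP library were miR-4463 with 11 reads, miR-7106-5p with 10 and miR-7854-3p with 9 reads in the QKI5 library. Against a floor of 3 reads they were at least 13.0-, 11.8- and 10.6-fold higher, a bound that leaves out the counting error of these reads. The lower limits of their exact counting intervals were 8.91, 7.96 and 7.01. With 0 reads in the QKI5 library, miR-548aj-3p had 35 reads in the GFP library and was at least 3.29-fold lower, and miR-548j-5p and miR-8060, with 19 reads each, were at least 1.78-fold lower, while the lower limits of the exact intervals were 2.53 for miR-548aj-3p and 1.31 for miR-548j-5p and miR-8060.

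**Figure D1:**
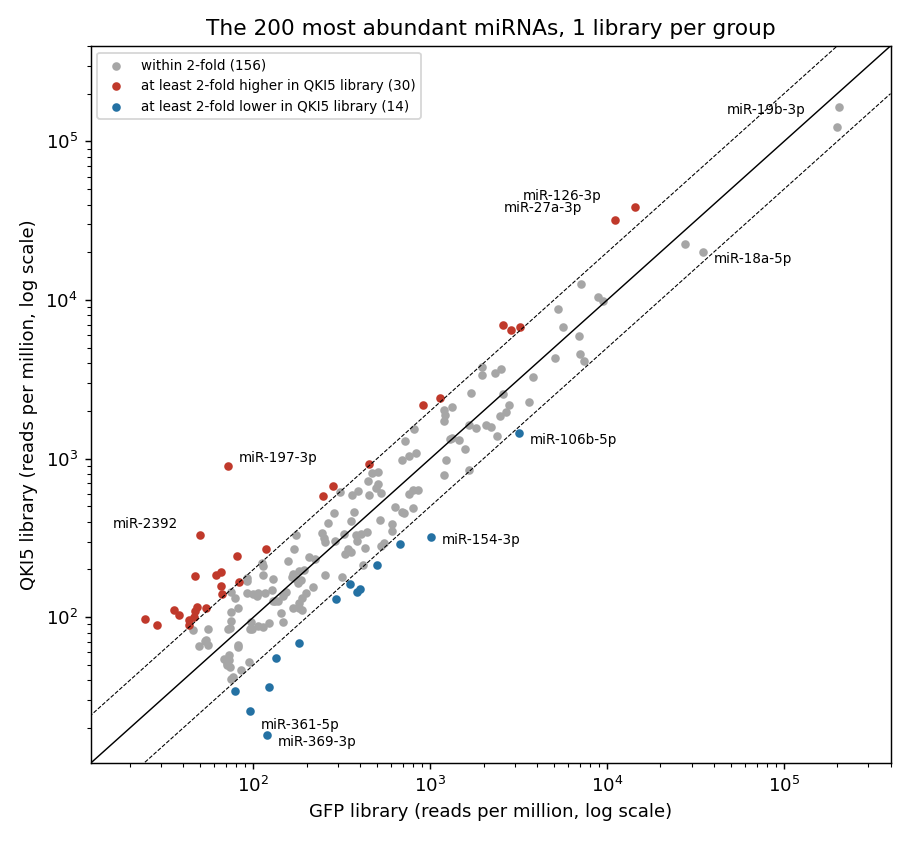
Level of each of the 200 most abundant miRNAs in the GFP library (x axis) and the QKI5 library (y axis), in RPM on log scales; each point is 1 miRNA, the solid line marks equal levels and the dashed lines 2-fold. The 30 red points are at least 2-fold higher with QKI5, led by miR-197-3p at 12.6-fold, and the 14 blue points at least 2-fold lower, led by miR-369-3p at 6.60-fold.

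Members of the let-7 family, which represses growth and stem cell genes, were higher with QKI5. Of the 6 let-7 miRNAs among the 400 most abundant, all 6 had a positive log2 ratio and 2 reached 2-fold. let-7e-5p was at 670 RPM against 282 RPM, 2.37-fold higher (2.28 to 2.46), let-7i-5p was 2.25-fold higher (1.79 to 2.82), let-7f-5p 1.89-fold (1.79 to 1.99) and let-7a-5p 1.63-fold (1.57 to 1.69). The log2 ratio of let-7e-5p was 0.97 with the GC trend removed, and that of let-7i-5p was 0.85 under quantile normalization, both under 2-fold. The median log2 ratio of the 20 detected members was 0.82, at percentile 99.9 of random lists. It was 0.54 with a pseudocount of 1 RPM, 0.46 with 10 times the pseudocount of 0.153 RPM, and 0.61 under quantile normalization. The floor median was 1.17, over 13 of the 20 members. Over its 6 members among the 400 the list lay at percentile 97.0, just inside. With the GC trend removed these 6 lay outside, at percentile 98.8 with a median of 0.90. let-7 members differ by few bases, and how reads matching several of them were assigned is not given.

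The family of miR-34 and miR-449, which includes the p53 target miR-34a, had a median log2 ratio of 1.19 over 11 detected members, at percentile 98.9. It was a family of low level here. miR-34a-5p, from an exon of MIR34AHG, was at 29 RPM with QKI5 and 4.34 RPM with GFP, 6.68-fold higher (5.22 to 8.59). miR-449c-5p was 3.77-fold higher (2.75 to 5.17), and these were its only members among the 400 most abundant. The family's median depended on low values. It was 0.56 with a pseudocount of 1 RPM, 0.50 with 10 times the pseudocount of 0.153 RPM, and 0.70 under quantile normalization. The floor median was 1.83, over 9 of the 11 members. The miR-23/27/24 clusters had a median of 0.56, at percentile 88.5. All 6 of their members among the 400 were above 0, and miR-27a-3p and miR-24-3p (2.34-fold, 2.24 to 2.44) exceeded 2-fold.

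The lists tied to blood lineages stayed inside the central 95%. Among miRNAs known to rise in red cell maturation, 0 of 12 among the 400 most abundant differed by 2-fold, 8 were above 0 and 4 below. The erythroid miR-451a was at 2187 RPM with QKI5 and 2798 RPM with GFP. Its neighbour miR-144-3p was 1.87-fold lower (1.78 to 1.96), and miR-210-3p was 1.91-fold higher (1.77 to 2.07). The list's median was 0.40, at percentile 64.2. Among miRNAs known to fall in red cell maturation, 3 of 10 were at least 2-fold higher and 0 lower. These were miR-24-3p, miR-130a-3p (2.79-fold, 2.06 to 3.77) and miR-25-3p (2.05-fold, 1.99 to 2.12). The log2 ratio of miR-25-3p was 0.93 when the 10 most abundant miRNAs were left out of the scaling and 0.52 with the GC trend removed. The list's median was 0.30, at percentile 54.3, and it turned to -0.05 under quantile normalization. Of 11 miRNAs studied in megakaryocytes, 5 were at least 2-fold higher, namely miR-126-3p, miR-27a-3p, miR-34a-5p, miR-130a-3p and miR-146a-5p. miR-10a-3p was 2.42-fold lower (1.71 to 3.52). The median of the megakaryocyte list was 0.36, at percentile 64.3, and its floor median was 0.83, over 15 of 17 members. The leukocyte list had a median of 0.36, at percentile 62.1. Both medians were 0 under quantile normalization. In it miR-146a-5p was 2.07-fold higher (1.86 to 2.29; log2 ratio 0.82 under quantile normalization) and miR-146b-3p 2.60-fold higher (1.93 to 3.49; log2 ratio 0.98 with the GC trend removed).

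The imprinted DLK1-DIO3 region at 14q32, which carries the largest miRNA cluster among the 400 most abundant miRNAs, lay lower as a group with QKI5 by its list, which leaves out some miRNAs of the region such as miR-2392. The 86 detected miRNAs of the list had a median log2 ratio of -0.29, at percentile 0.160 of random lists. With a linear trend on GC content removed the list lay inside the central 95%, with a median of -0.10 at percentile 6.06, and its 68 members among the 400 most abundant had a median of -0.02 at percentile 16.4. Of these 68, as deposited, 41 were below 0 and 27 above, 7 were at least 2-fold lower and 6 at least 2-fold higher, and miR-369-3p and miR-539-5p had the lowest and highest log2 ratios of these 68. The miR-17-92 cluster and its paralogs had a median of -0.22, at percentile 7.53, with 15 of 21 members below 0. With a pseudocount 10 times as large that list lay outside the central 95%, at percentile 0.895, and with the GC trend removed it lay just inside, at percentile 2.56, while its 21 members among the 400 lay outside, at percentile 1.63. In the paralog cluster inside MCM7, miR-106b-5p was 2.19-fold lower (2.14 to 2.23) while miR-25-3p was 2.05-fold higher. The log2 ratio of miR-106b-5p was -0.97 when the columns were rescaled to the sum of the listed miRNAs. The miR-15/16 family had a median of -0.28, at percentile 5.07, with miR-15b-5p 1.95-fold lower (1.90 to 2.01), miR-424-3p 3.21-fold lower (2.03 to 5.36) and miR-16-5p higher. miR-424-5p, the other arm of miR-424, had a log2 ratio of 0.74. Over its members among the 400 most abundant the miR-15/16 list lay at percentile 1.78 with a median of -0.42, and with the GC trend removed at percentile 14.1 with a median of -0.15. Its floor median was 0.04, over 12 of its 13 members. Medians were -0.23 for the miR-29 and miR-30 families (percentile 8.62), with miR-29b-3p at a ratio of 0.855 (log2 ratio -0.23, and 0.05 with the GC trend removed), miR-29c-5p at 1.80 and miR-30d-3p 2.54-fold lower. They were -0.34 for miR-181 (13.3), with miR-181a-5p at 0.796, miR-181b-5p at 0.608 and miR-181a-3p 2.15-fold lower (log2 ratio -0.94 when rescaled to the sum of the listed miRNAs and -0.96 with the GC trend removed). For miRNAs of the HOX loci the median was -0.18 (8.14), and the floor median was 0.08, over 9 of 10 members. There miR-10a-5p stood at a ratio of 0.795 (log2 ratio -0.33, and 0.03 with the GC trend removed) and miR-196a-5p was 2.91-fold higher (2.53 to 3.36).

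**Figure D2:**
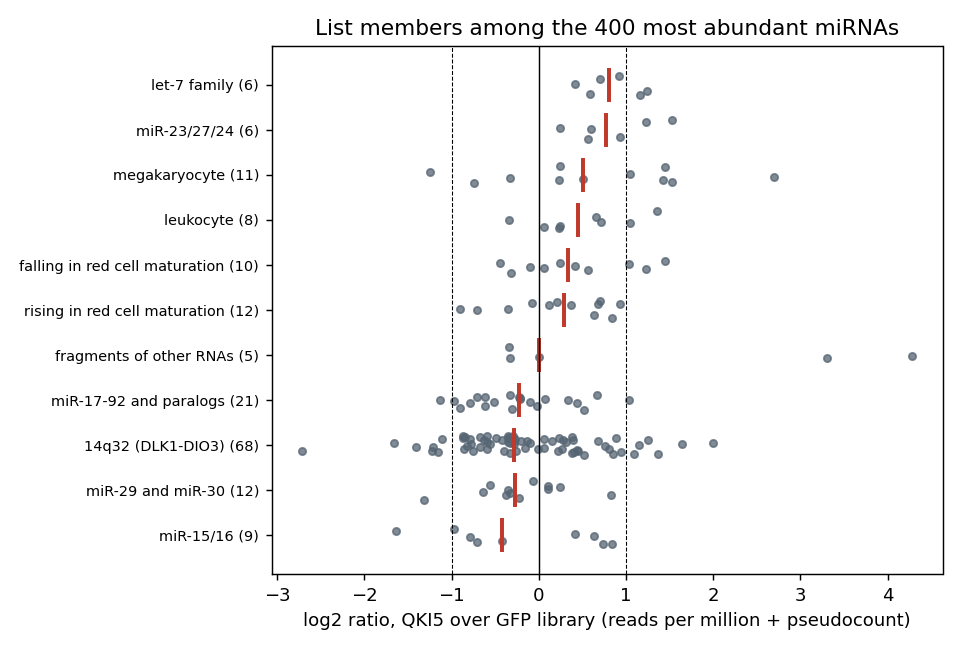
Log2 ratio of QKI5 over GFP (x axis) for the members of 11 lists among the 400 most abundant miRNAs; each point is 1 miRNA, its height within a row is random, red bars are medians, dashed lines mark 2-fold, and counts of members are in brackets. The 6 let-7 miRNAs all lie above 0, whereas 41 of the 68 miRNAs of 14q32 lie below 0.

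Muscle miRNAs reached at most 2.02 RPM (median -0.36, percentile 37.0), and the placental and stem cell clusters at most 1.37 RPM (median -0.36, percentile 47.4). Both medians rest on a few reads. The floor medians were 0.84 over 4 of 9 muscle members and 1.25 over 12 of 51 placental and stem cell members. Epithelial miRNAs reached at most 41.7 RPM, with a median of 1.19 at percentile 98.9, yet their most abundant members diverged. miR-200c-3p was 1.65-fold higher (1.43 to 1.91) and miR-141-3p 1.38-fold lower (1.17 to 1.62). With GFP reads thinned to the QKI5 total in 1 random draw the epithelial list lay at percentile 90.9, with a median of 0.90. With a pseudocount 10 times as large it lay at 97.0, with a median of 0.45. The median was 0.59 with a pseudocount of 1 RPM. Neuronal miRNAs had a median of -0.05 (percentile 63.4), which turned to 0.08 when the columns were rescaled to the sum of the listed miRNAs. Their floor median was 0.21, over 14 of 22 members. Among them miR-128-3p stood at a ratio of 1.14, miR-132-3p at 0.676 and miR-129-5p at 2.76. Stromal and endothelial miRNAs had a median of 0.42 (89.2), led by miR-126-3p, with miR-10b-5p at a ratio of 0.598. Liver and gut miRNAs had a median of 0.24 (55.8), which turned to -0.05 under quantile normalization and to -0.18 with the GC trend removed, with miR-192-5p higher and miR-194-5p at a ratio of 1.45. Drosha-independent miRNAs had a median of 0.51 (94.5). In the same draw of thinned GFP reads the list lay just outside the central 95%, at percentile 97.52. Other draws were not compared for the lists. Of the Drosha-independent miRNAs, miR-484 was 1.44-fold higher (1.35 to 1.52) and the mirtron miR-877-5p 4.82-fold higher (3.79 to 6.16). Entries that overlap other structural RNAs, and may be fragments of them, had a median of 1.23 over 8 members, at percentile 98.4. That median rests on low entries, and with a pseudocount of 1 RPM it was 0.32, at percentile 67.6. miR-1246 was 23.5-fold higher (13.8 to 42.6; 106 and 16 reads) and miR-1973 10.7-fold higher (7.31 to 16.1; 109 and 36 reads), while the abundant miR-1260a was 1.27-fold lower (1.24 to 1.29). Of the 22 lists, 5 lay outside the central 95%. Lists share members and transcripts and so are not independent.

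The arms of 1 hairpin often differed in their ratio. Among 102 hairpins with both arms among the 400 most abundant miRNAs, 44 had arms with log2 ratios of opposite sign, and 41 had arms that differed by at least 2-fold. Of the 102, 6 overlap a miRNA hairpin on the other strand, among them miR-423 and miR-3184, and their reads cannot be taken as separate. Without these 6 the counts were 41 and 37 of 96. Across these hairpins the log2 ratios of the 5p and 3p arms had a Spearman's rho of 0.109 (bootstrap 95% interval -0.0872 to 0.312), and across 579 hairpins with both arms detected it was 0.0696 (-0.0109 to 0.149). Hairpins are not independent replicates. miR-369-3p was 6.60-fold lower with QKI5 while miR-369-5p stood at a ratio of 1.18 (1.12 to 1.24). miR-106b-5p was 2.19-fold lower while miR-106b-3p was 1.59-fold higher (1.5 to 1.68), and miR-15b-5p and miR-144-3p were lower while miR-15b-3p was 1.34-fold higher (1.24 to 1.44) and miR-144-5p 1.61-fold higher (1.41 to 1.83). The other arms of miR-361-5p, miR-652-5p and miR-539-5p also went the opposite way, with log2 ratios of 1.32, 1.42 and -1.11. Both arms of miR-126 and of miR-27a were higher with QKI5.

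The log2 ratio went with the base composition of the miRNA. Across 399 of the 400 most abundant miRNAs, the GC content of the hairpin arm and the log2 ratio had a Spearman's rho of 0.355 and a Pearson's r of 0.343, and a linear trend took up 11.7% of the variance. Among the 100 miRNAs with the lowest GC content, 25.6% to 41.9%, the median log2 ratio was -0.33, and among the 100 with the highest, 55.9% to 79.1%, it was 0.49. At least 2-fold higher levels with QKI5 were seen for 6 of the 100 with the lowest and 38 of the 100 with the highest GC content. MiRNAs are not independent replicates, and the trend was noticed in these data. The 14q32 list had a median GC content of 44.3% and the let-7 list 46.9%. With the linear trend removed, the median of the 14q32 list moved from -0.29 to -0.10, at percentile 6.06, and that of let-7 from 0.82 to 0.91, at percentile 99.99. The structural RNA list moved to 0.17, at percentile 40.1, the epithelial list to 0.81, at percentile 95.5, and the Drosha-independent list, with a median GC content of 65.6%, to -0.11. The high entries of the structural RNA list did not fall, with miR-1246 going from 4.28 to 4.40 and miR-1973 staying at 3.30. Its abundant entries miR-1260a, miR-1260b and miR-4454 went down to -0.52, -0.26 and -0.60.

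**Figure D3:**
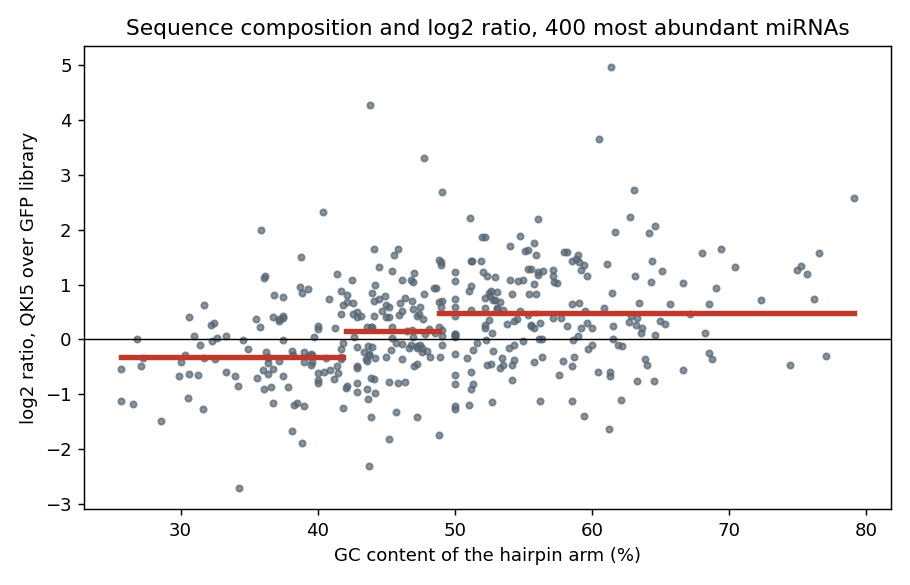
Log2 ratio of QKI5 over GFP (y axis) against the GC content of the hairpin arm in percent (x axis) for 399 miRNAs; each point is 1 miRNA and the red lines are medians of 4 bins of GC content. The medians go from -0.33 in the lowest bin to 0.49 in the highest.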

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

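The rescaling to the sum of the listed miRNAs and the tests on composition, depth and reads were chosen after the data were seen; the other settings were fixed before. The count of higher miRNAs was 30 and that of lower ones 14. Rescaling to the sum of the listed miRNAs moved the median log2 ratio of the 200 by 0.16 (41 higher, 12 lower) and leaving the 10 most abundant out of the scaling by -0.11 (23 and 18). Quantile normalization gave 18 higher and 20 lower, and the cause was not tested. By construction, the counts followed the number of miRNAs considered and the threshold: 11 higher and 4 lower among the top 100, 83 and 29 among the top 400, 475 and 145 among all detected miRNAs, and 7 and 4 at 3-fold. Among all detected miRNAs the pseudocount and the depth tilt the counts toward higher. There 1 QKI5 read against 0 gave a log2 ratio of 1.0 (miR-124-3p), while 2 GFP reads against 0 gave -0.64 (miR-124-5p). Among the 200 most abundant miRNAs, an exact binomial test of the reads, which compares only these 2 libraries, called 97 higher and 85 lower at any fold. The other settings for these counts stayed within 1.5 times. The number of lists outside the central 95% was 5, and 4 or 5 in each other scaling or pseudocount except with the GC trend removed, where it was 2 (let-7, and miR-34 with miR-449). It was also 2 with members limited to the top 400 (miR-15/16 and 14q32, both inside once the GC trend is removed), where let-7 and the structural RNA list lay inside, and the epithelial list and miR-34 with miR-449 had too few members. With the GC trend removed, let-7 and the miR-17-92 list lay outside over their members in the top 400, at percentiles 98.8 and 1.63. Of the 30 higher and 14 lower miRNAs, 14 and 10 were kept in all 10 settings of scaling, pseudocount, depth and composition, counting the deposited values as 1. The rho between arms of 0.0696 was 0.109 among the top 400. No paired analysis was possible because each group has 1 library. Depth limits miRNAs such as miR-124, at 1 and 2 reads.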

Other observations

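The tests on counting error and on structural RNA fragments were chosen after the results were seen; the others were written before their result was known. Some miRNA genes that sit side by side had ratios on the same side, and these clusters were picked after their values were seen. In the cluster on chromosome X that holds miR-660, whose hairpin lies in an intron of CLCN5, 6 of 7 miRNAs, counting only the more abundant arm of each hairpin, had a positive log2 ratio and 4 were at least 2-fold higher with QKI5, among them miR-188-5p (3.43-fold, 2.80 to 4.20), miR-660-5p (3.13-fold), miR-532-5p (2.42-fold, 2.24 to 2.62) and miR-501-3p (2.25-fold, 1.85 to 2.73), while miR-362-3p stood at a ratio of 0.743. The other arms went both ways, with log2 ratios of -0.60 for miR-188-3p and 1.88 for miR-500a-3p. In the cluster of miR-99b, let-7e and miR-125a on chromosome 19 the more abundant arms of all 3 were higher, with miR-99b-5p at 1.56-fold (1.52 to 1.59) and miR-125a-5p at 1.45-fold (1.43 to 1.48). Outside the lists and the 200, miR-935 was 6.19-fold higher (4.69 to 8.22) and miR-628-5p 5.18-fold higher (3.91 to 6.89), both picked after their values were seen.

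The first pattern is that GC-rich miRNAs tended to be higher and AU-rich ones lower in the QKI5 library. With the GFP reads thinned to the QKI5 total, the lowest of 20 values of rho was 0.347, against 0.355 unthinned. Thinning keeps the expected level of each miRNA, and these miRNAs are abundant, so it could hardly have lowered rho. It shows only that the number of reads by itself does not make this pattern. A composition bias between the libraries may account for the pattern, and was tested between the arms of a hairpin, which share 1 transcript. The rho of arm GC difference and arm log2 ratio difference was 0.155 over 102 hairpins, below the upper limit of 0.196 of 10000 shuffles, with an interval of -0.0487 to 0.349. An effect of QKI5 on whole hairpins would leave little slope between arms. That slope was 0.22 per 10% GC (-0.15 to 0.61) against 0.25 between hairpins (0.13 to 0.37). These explanations cannot be told apart here. The arms of a hairpin mostly differed little in GC content beside the range across miRNAs, 25.6% to 79.1%. That content was taken from the sides of the hairpin, not from the mature miRNAs. Hairpins were also few, with 1 library per group.

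The second pattern is the 12 highest log2 ratios, led by miR-197-3p. With the linear GC trend removed their median went from 1.62 to 1.42, and the lowest of 10000 bootstrap fits gave 1.20. That trend was 0.32 on the log2 scale per 10% GC, too shallow to bring ratios picked as the highest near 0. The values show that the linear trend leaves most of their size, and do not exclude another composition bias. The lowest of the 12 lower limits of the log2 read ratio was 1.29. With at least 119 reads in either library, ratios picked as the highest had to have limits above 0. The limits show only that read counting alone does not give ratios of this size. Another composition bias, a difference between cultures or library preparations and an effect of QKI5 remain open, since the design has 1 library for each. That these miRNAs may respond to QKI5 is a hypothesis that needs replicate libraries.

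The third pattern is in entries with structural RNA sequence. miR-4485, picked after its value was seen, had the largest log2 ratio among the 400 most abundant miRNAs, with 92 reads in the QKI5 library and 7 in the GFP library (46.6-fold, 21.8 to 119), followed by miR-1246. GENCODE places the hairpins of miR-4485 and miR-1973 in exons of MTRNR2L8 and MTRNR2L13, which are copies of mitochondrial ribosomal RNA sequence. Breakdown of structural RNAs in general would raise all such entries. For the 3 most abundant, miR-1260a, miR-1260b and miR-4454, the highest upper limit of the log2 read ratio was 0.039, so these were barely if at all higher. The lowest lower limit for miR-4485, miR-1246 and miR-1973 was 2.87. Those were picked for their high ratios, so the gap itself is no support. Breakdown of only some structural RNAs was not tested. A higher level of mitochondrial fragments may remain for miR-4485 and miR-1973 and was not tested. GENCODE gives no host gene for miR-1246.

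It was asked whether neighbours on 1 primary transcript change together. Over 75 pairs of neighbouring miRNA genes within 10 kb, with 1 arm for each, the median absolute difference in log2 ratio was 0.69, against a median of 0.90 for random pairs and a 2.5th percentile of 0.68, so the pairs may be more alike than random ones but this was not settled. It was also asked whether the QKI motif ACUAAY within the hairpin goes with a change. The 11 miRNAs with the motif among 399 searched, among them miR-379-5p (2.37-fold higher) and miR-758-3p (2.33-fold lower), had a median log2 ratio of -0.27. That lay at percentile 13.8 of random lists (central 95% -0.43 to 0.77), which leaves the question open. Both arms of miR-142, miR-379, miR-411 and miR-744 are among the 11, though the motif belongs to the hairpin. miR-379, miR-411 and miR-758 are on the 14q32 list, which itself lay lower. Random lists drew each miRNA separately, and a median cannot show changes that go both ways. Motifs beyond the hairpin were not searched.

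miR-103b, whose hairpin lies antisense to that of miR-103a, had 0.354 reads per miR-103a-3p read in the QKI5 library and 0.353 in the GFP library. Both were listed at least 2-fold higher with QKI5, so they count as 2 of the 30 although their reads cannot be taken as separate. The same holds for miR-550a-3p and miR-550b-2-5p, 2 of the 14 lower, with 0.369 and 0.335 reads of the second per read of the first. miR-3184-3p, antisense to miR-423, had 0.337 and 0.336 reads per miR-423-5p read.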
